A study of Mus musculus with 13 samples.

How the data were processed

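Total RNA from frozen mouse liver was amplified with the WT-Ovation Pico system and hybridised to single-colour Affymetrix arrays, per the labels' protocols. The values deposited by the authors were 1 intensity per probe set and array for 35556 probe sets on 13 arrays. The submitters' processing notes name RMA, without a version, and Affymetrix Expression Console 1.1, with no role for either, and the genome build and probe positions were not given in the sources used here, so no coordinates are printed. The deposited intensities were linear, from 0.000427 to 17831, and their distributions differed between arrays (median intensity 48.2 to 82.99), although the design fixed before the data were examined had assumed log2 values that needed no further scaling. The test was therefore adapted to the unit, and quantile normalization, planned as an alternative, became the main setting, while the fit without it was kept as an alternative added after seeing the data.

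The intensities were quantile-normalized over the 13 arrays with limma 3.58.1 in R 4.3.3, and log2 of the value plus 16 was taken, which understates changes of dim genes. The offset was chosen after the range of the intensities had been seen. GEO's annotation of the array listed 23410 probe sets, of which 21789 had 1 gene symbol and 1621 several, and 12146 were not listed and stay unnamed here. Symbols were updated through Entrez IDs for 21698 of the 21789 with a table of mouse genes of assembly GRCm38.p6, used for names only. Probe sets with several symbols named no gene. Of different probe sets of a gene the one with the highest mean was used, giving 19938 genes. Other probe sets of Acaca, Pdia4 and Slbp changed in the opposite direction to the one used. Genes with a mean below the 25th percentile were left out, and 14953 were tested.

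Groups and replicate numbers were taken from the labels, and no sample was left out. A single limma model (lmFit and eBayes) over all 13 arrays held the 5 groups and a term for array batch, with 7 residual degrees of freedom. Batches came from the run named in the labels' raw array names, and the batch term itself called 2187 genes. Arrays of all groups shared one estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each comparison, and every adjusted p of a gene is from this limma model. The 7 comparisons fixed before the data were examined were DEN in wild type, and the comparisons of the 4 genotypes after DEN with each other, and 3 comparisons of the remaining genotypes with untreated wild type were added afterwards. Changes of genes are given as log2 change ± SE and levels of groups as mean ± SD.

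Gene lists of pathways, liver functions and cell types were also fixed before the data were examined. Of 674 list entries, 54 found no probe set with a single symbol and 3 were matched through an older symbol. Well-known members were thereby left untested. Cdkn1a, Bax and Gdf15 of the p53 list had no such probe set. E2f1, E2f2, Ccne1, Cdc6 and Mcm5 of the E2F list were among those removed by the filter on dim genes. The 26 lists with at least 5 tested members entered limma's camera with a preset correlation of 0.01 between genes, adjusted over the 26 lists of a comparison. Camera with an estimated correlation and fry were run beside it, and of 77 calls 5 held with the former and 32 with the latter. The mean of a list's members in each array, fitted in the same model, gives list differences with 95% intervals. These intervals use 1 spread pooled over all groups. For the G2/M list the knockout arrays differed by -1.71 (array 2 minus array 1), against a residual SD of 0.131 in the other groups. Its intervals are therefore wide for comparisons without the knockout arrays and may be too narrow for those with them. A list's median, mean and test had the same sign for every call.

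Named genes followed a rule fixed before the data were examined: Rb1 first, then up to 8 genes per direction with the largest change among those called in the main comparisons and up to 4 in others, leaving out predicted loci, small RNAs, Xist and Y-linked genes, then up to 4 members with the smallest p from each list with a call, and the 3 genes of smallest p where none was called. Other genes, such as the muscle genes of a single array, were chosen after their values were seen.

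The model was tested on simulated data with the real genes, means and spread, with 200 genes changed in each comparison. It recovered 66% of genes changed by a log2 of 2 for DEN in wild type, 88% for N750F against wild type, 95% for N750F against heterozygous, 77% for knockout against wild type, 79% for knockout against heterozygous, 75% for heterozygous against wild type and 86% for N750F against knockout. At a log2 of 1 it recovered 10%, 42%, 40%, 13%, 13%, 18% and 25% in the same order. False calls ran from 1 of 91 calls (knockout against wild type) to 10 of 145 (N750F against heterozygous), with 7 of 83 for DEN. Each gene had 1 spread for all arrays, whereas the real arrays differed in spread (interquartile range of deviations from gene medians 0.315 to 0.735). Recovery in the real data may therefore be lower. Similarity between comparisons was set against 100 simulations of unchanged groups. These drew each gene independently, so their ranges leave out genes that vary together and may be too narrow.

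Alternatives were a fit without the batch term, each batch alone, batch as a random block, the replicate number as a block, no filter, a stricter filter at the 50th percentile, all probe sets, median centring, no normalization, offsets of 1 and 50, limma's trend and robust options, array quality weights, a fold change of at least 2, an adjusted p under 0.10, the Y-linked level as a covariate, only the groups compared, the 2 arrays of widest spread left out, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.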

Results

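Liver RNA from 14-day-old mice was measured on 13 Affymetrix arrays, 1 array per mouse as far as the labels say. The mice carried combinations of floxed Rb1, wild type Rb1 and the N750F allele, and Cre recombinase was driven by the albumin promoter, which is active in hepatocytes. Rb1 encodes the retinoblastoma protein, which binds E2F transcription factors and restrains entry into S phase. The N750F substitution alters the site through which the protein contacts partners that carry an LXCXE motif. Diethylnitrosamine (DEN) is a liver carcinogen that cytochromes P450 convert into a DNA-alkylating agent, and it was given as a single intraperitoneal dose of 20 mg/kg 24 h before the livers were taken. The groups were untreated wild type (2 arrays), wild type with DEN (2), heterozygous with DEN (2), N750F with DEN (5) and knockout with DEN (2). Wild type here means floxed Rb1 without Cre, and knockout means floxed Rb1 with Cre. Comparisons of heterozygous or knockout livers with wild type thus also change the presence of Cre. The description of the N750F group names the mutant alone, without its other allele or Cre. Heterozygous means 1 functional and 1 floxed allele with Cre, although another field of the same labels carries the genotype tag LOH for these 2 arrays. The comparisons ask how wild type liver responds to DEN and how livers of the Rb1 genotypes differ after it. The untreated arrays were of wild type alone, so a difference between genotypes that was there before DEN is not separated from a different response to it. Nothing in the labels says whether mice of a group came from separate litters, so the p-values measure the spread between these arrays. The small number of arrays limits the precision of every value.

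The arrays were run in 2 batches, batch 1 with 9 arrays and batch 2 with 4. Median deposited intensities were 76.9 to 82.99 in batch 1 and 48.2 to 73.3 in batch 2. Both untreated and both knockout arrays lay in batch 1, wild type and heterozygous DEN had 1 array in each batch, and N750F had 3 and 2. Xist, the non-coding RNA of the inactive X chromosome, and the Y-linked genes gave the same sex for every mouse. Untreated mice were 1 male and 1 female, wild type DEN mice were 2 females, heterozygous mice 2 males, N750F mice 1 male and 4 females, and knockout-labelled mice 2 males. Wild type DEN mice thus differed in sex from every heterozygous and every knockout-labelled mouse. Heterozygous array 4 had a Y-linked mean of 9.34 and an intermediate Xist level of 8.05. No pair of arrays held identical values (0 of 78 pairs), and correlations across probe sets were 0.876 to 0.973 within groups and 0.824 to 0.963 between groups.

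The targeted gene Rb1 (probe set 10421526) was read in every array first. Its normalized log2 level was 7.27 and 7.15 in the untreated arrays, 8.04 and 8.01 in wild type DEN, 7.92 and 7.62 in heterozygous DEN, and 7.82 to 8.43 over the 5 N750F arrays. The 2 knockout arrays had 7.92 and 6.57. The position of this probe set relative to the floxed part of the gene was not known here, so its level does not check the labels. Knockout array 1 lay below both wild type DEN arrays, but within the N750F range and above the heterozygous array at 7.62. The 2 arrays are therefore called knockout-labelled. Knockout-labelled minus wild type DEN was -0.87 ± 0.37 (SE, adjusted p = 0.544), and knockout-labelled minus heterozygous was -0.61 ± 0.37 (adjusted p = 0.646). The second of these changed sign to 0.070 without knockout-labelled array 2. That array also held some transcripts of skeletal muscle, and 8 of 11 measured muscle genes were highest in it. Tnnt3, fast muscle troponin T, was at 11.96 against at most 6.18 in any other array, and Tnnc2, fast muscle troponin C, at 10.49 against at most 5.73. The other 3, Ckm (8.25 against 8.98 in another array), Atp2a1 (7.46) and Myl1 (5.38 against 5.55), were not.

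Of 14953 genes tested, the numbers past an adjusted p of 0.05 ran from 0 for N750F against knockout-labelled livers to 928 for N750F after DEN against untreated livers. Gene lists fixed before the data were examined were tested with a preset correlation between genes. Over the 10 comparisons, 5 list calls held when the correlation was estimated: E2F targets, G2/M genes, cytochromes P450 and NRF2 targets in N750F against heterozygous livers, and p53 targets in knockout-labelled against untreated livers. No comparison had 3 or more arrays in both groups, and these counts were not tested by regrouping the arrays.

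**Figure D1:**
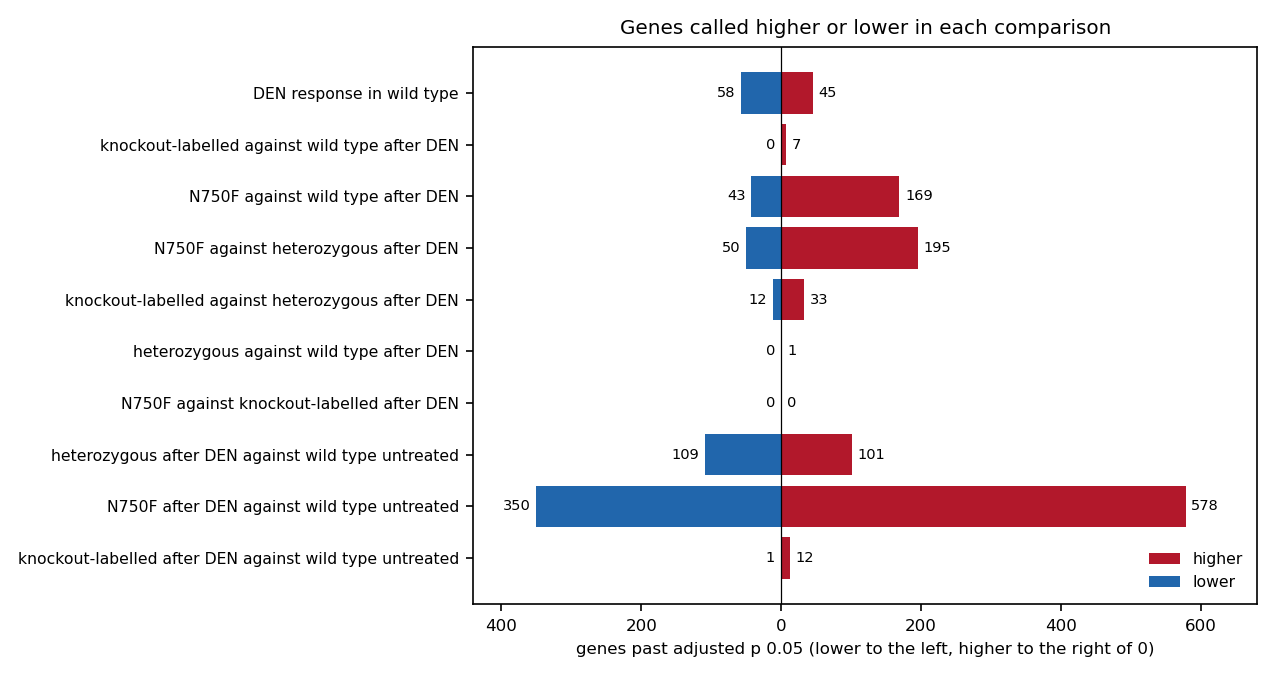
Number of genes called in each comparison (x axis, genes past an adjusted p of 0.05), lower to the left and higher to the right of 0, for the 10 comparisons on the y axis. N750F against wild type had 169 higher and 43 lower, and N750F against heterozygous 195 higher and 50 lower, while heterozygous against wild type had 1 gene in all.

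DEN in wild type liver raised 45 genes and lowered 58. Sult1e1, estrogen sulfotransferase, rose by a log2 change of 4.19 ± 0.60 SE (adjusted p = 0.0102, 2 arrays against 2), from 4.60 ± 0.24 to 8.82 ± 0.39 (SD, n = 2 each). Its levels in untreated and N750F livers (4.60 and 4.83) lay near those of Y-linked genes in females (4.44 to 4.61), so the size and rank of its changes here and below depend on the offset, with 5.51 at an offset of 1 and 3.05 at 50 for DEN. The largest fall was in Igf2, the fetal insulin-like growth factor, at -4.63 ± 0.52 (adjusted p = 0.00428), from 12.60 ± 0.15 to 8.30 ± 0.07. Both DEN arrays lay beyond both untreated arrays for each of the 16 genes of largest change. These included the rises of Ddias (2.89 ± 0.39), the cytochrome P450 gene Cyp4f14 (2.66 ± 0.32), and Ephx1, microsomal epoxide hydrolase (2.64 ± 0.30). The falls included Peg3, an imprinted growth regulator (-2.79 ± 0.41), Fabp5 (-2.65 ± 0.52) and Igfbp4 (-2.47 ± 0.37).

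Among 26 measured p53 targets, 5 rose and 21 did not pass, with a median change of 0.55 and 8 higher when adjusted over the list alone. The list had an adjusted p = 4.91e-08, but adjusted p = 0.0984 with an estimated correlation. Ccng1, cyclin G1, rose by 1.87 ± 0.23, Phlda3, an inhibitor of AKT, by 2.08 ± 0.33, and Mdm2, the p53 ubiquitin ligase, by 1.59 ± 0.32. Of 27 NRF2 and glutathione genes, 5 rose, 1 fell and 21 did not pass (adjusted over the list alone, 10 and 1). Gstp1 was up by 1.87 ± 0.33, Ugdh up by 1.80 ± 0.32 and Osgin1 down at -1.80 ± 0.31 (list adjusted p = 3.3e-10, adjusted p = 0.0984 with an estimated correlation). From 30 cytochromes P450 and drug metabolism genes, 3 rose and 27 did not pass (9 higher adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), led by Cyp2c38 (2.50 ± 0.31), Cyp2c54 (2.87 ± 0.58) and the glucuronosyltransferase Ugt2b1 (1.51 ± 0.29).

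Of 38 G2/M genes, 4 fell and 34 did not pass, with a median of -1.11 and 16 lower when adjusted over the list alone. The list had an adjusted p = 8.07e-15, but adjusted p = 0.279 with an estimated correlation, and its mean differed by -1.15 (95% interval -2.33 to 0.03). The width of that interval came mostly from the spread between the 2 knockout-labelled arrays, which are in neither group. Plk1 (-2.14 ± 0.41), Ccnb2 (-1.71 ± 0.31) and Cdc20 (-1.70 ± 0.33) encode a mitotic kinase, cyclin B2 and an activator of the anaphase-promoting complex. None of the 38 E2F targets of DNA replication passed, with 0 called by limma over all genes and 0 adjusted over the list alone. The list median was -0.41 (adjusted p = 0.552 with an estimated correlation). In this list too the knockout-labelled arrays lay apart, by -0.84 (array 2 minus array 1) against a residual SD of 0.174 in the other groups. They enter the spread used for each gene, so the lack of calls does not show that E2F targets were unchanged by DEN. Fetal liver and imprinted growth genes had 4 falls among 15, with 11 not passing and 9 lower adjusted over the list alone. Beside Igf2 and Peg3 these were Cd24a (-2.21 ± 0.43) and Cdkn1c, an imprinted cell cycle inhibitor (-1.66 ± 0.30). The fetal list mean differed by -1.38 (95% interval -1.93 to -0.83, adjusted p = 0.0984 with an estimated correlation).

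Of 16 macrophage and Kupffer cell genes, 3 fell and 13 did not pass (10 lower adjusted over the list alone, median -1.03, adjusted p = 0.0984 with an estimated correlation). They were Csf1r (-2.03 ± 0.36), Cd5l (-1.72 ± 0.33) and lysozyme, Lyz2 (-1.32 ± 0.25). S100a8, a single member of the 7 tested neutrophil genes, fell by 2.37 ± 0.35. Erythroid, endothelial and stellate lists had medians of -0.44, -0.36 and -0.42 with no member called by limma (adjusted p = 0.21, 0.279 and 0.21 with an estimated correlation, and 2, 3 and 1 lower adjusted over the list alone). Within batch 1 alone, where wild type DEN had a single array, the calls did not include any of the 103 genes. The count was 4 without untreated array 1, 43 without untreated array 2, 147 without wild type DEN array 3 (25 higher and 122 lower, 35 of the 103 among them), 15 without wild type DEN array 4, 52 to 67 without some heterozygous or N750F arrays, and 226 without either knockout-labelled array. It was 26 with the Y-linked level as a covariate.

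**Figure D2:**
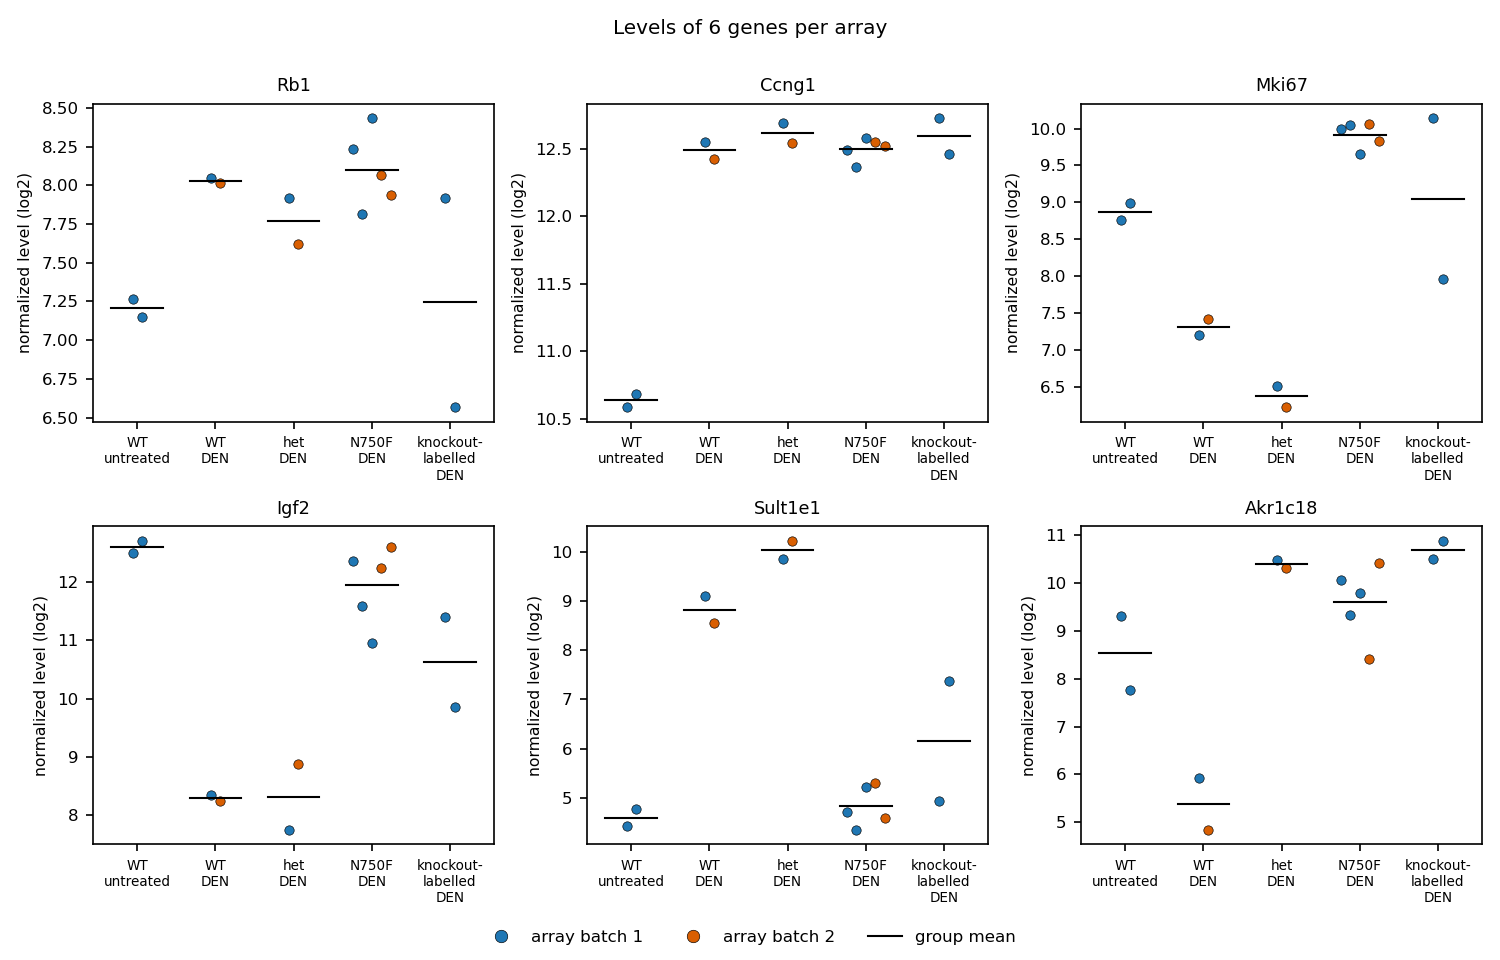
Normalized log2 level (y axis) of Rb1, Ccng1, Mki67, Igf2, Sult1e1 and Akr1c18 in each of the 13 arrays by group (x axis), with the group mean as a line and the array batch as the colour; WT is wild type and het is heterozygous. The 5 N750F arrays lay between 10.96 and 12.60 for Igf2, above both wild type DEN arrays at 8.35 and 8.25, and Rb1 was at 7.92 and 6.57 in the knockout-labelled arrays.

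The other genotypes after DEN were also set against untreated wild type livers, as comparisons added after the data had been seen. Targets of p53 were higher in each of them: 7 of 26 passed in heterozygous livers, 8 in N750F and 4 in knockout-labelled ones. The list had medians of 0.71, 0.71 and 0.86 and 10, 13 and 12 genes higher when adjusted over the list alone. With an estimated correlation the adjusted p was 0.0727, 0.186 and 0.0405. Ccng1 rose by 2.00 ± 0.23, 1.88 ± 0.20 and 1.96 ± 0.22, close to its 1.87 in wild type, and Polk, a translesion DNA polymerase, by 2.49 ± 0.38, 2.32 ± 0.31 and 2.20 ± 0.36. Heterozygous livers had 101 genes higher and 109 lower, N750F livers 578 and 350, and knockout-labelled livers 12 and 1. Of the 103 genes called in wild type, 68, 54 and 8 were also called in these 3 comparisons, which share the untreated arrays with it, so an overlap arises in part from those arrays.

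In these comparisons genotype and DEN change together. In heterozygous livers 6 of 38 G2/M genes fell and 32 did not pass, with a median of -1.37 (28 lower adjusted over the list alone, adjusted p = 0.237 with an estimated correlation). Ube2c (-3.16 ± 0.47) and Plk1 (-2.79 ± 0.41) were among them. N750F livers had 4 of the 38 higher than untreated livers and 34 not passing, with a median of 0.91 (10 higher adjusted over the list alone, adjusted p = 0.532 with an estimated correlation). Among the 4 were Cep55 at 1.49 ± 0.36 and Prc1 at 1.44 ± 0.39. Of 38 E2F targets in N750F livers, 10 rose and 28 did not pass (10 higher adjusted over the list alone, adjusted p = 0.532 with an estimated correlation). Examples were Mcm7, a subunit of the replicative helicase (1.93 ± 0.40), and Rrm1, of ribonucleotide reductase (1.72 ± 0.35). Knockout-labelled livers had medians of 0.38 for E2F targets and 0.37 for G2/M genes with no member called by limma (adjusted p = 0.545 and 0.583 with an estimated correlation). Without knockout-labelled array 1 these became 0.030 and -0.31. In heterozygous livers 9 of 27 NRF2 and glutathione genes rose and 18 did not pass (21 higher and 1 lower adjusted over the list alone, adjusted p = 0.0648 with an estimated correlation), including Nqo1, a quinone reductase (3.26 ± 0.44). Igf2 fell by 4.61 ± 0.52 there and Gpc3, a fetal glypican, fell by 2.10 ± 0.33. N750F livers also had 4 of 28 interferon response genes higher, such as Cmpk2 (1.51 ± 0.37), with 24 not passing, 5 higher adjusted over the list alone and an adjusted p = 0.532 with an estimated correlation. This was uneven: the list mean was 8.20 in N750F array 1, 7.21 to 7.76 in the other 4, and 7.26 and 7.04 in the untreated arrays, and the median change of 0.65 became 0.34 without N750F array 1 and 0.35 without untreated array 2.

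Without untreated array 1, 28 genes passed in heterozygous livers, 13 in N750F and 8 in knockout-labelled ones, and without untreated array 2 the numbers were 104, 254 and 0. Counts without an array of the treated group fell to 60 and 32 in heterozygous livers (arrays 3 and 4), 443 and 160 in N750F (arrays 2 and 3), and were 46 without either knockout-labelled array (24 higher and 22 lower without array 1, 32 and 14 without array 2). Batch 1 alone gave 2, 286 and 7.

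Comparing N750F with wild type livers after DEN, 169 genes were higher and 43 lower. The largest differences were those of Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase (4.17 ± 0.47), Igf2 (3.72 ± 0.41), Anln, the cytokinesis protein anillin (3.55 ± 0.47), and Birc5, survivin (3.45 ± 0.61). On the lower side they were Sult1e1 (-3.98 ± 0.48), Cyp2c54 (-2.86 ± 0.46), Cyp2c50 (-2.81 ± 0.42) and the proline dehydrogenase Prodh (-2.24 ± 0.35). Adjusted p-values of these 8 were 0.00235 to 0.0134, and all 5 N750F arrays lay beyond both wild type arrays for each. Igf2 averaged 11.95 ± 0.67 in N750F (SD, n = 5) against 8.30 ± 0.07 (n = 2). Akr1c18 was at 5.93 and 4.84 in the wild type DEN arrays and at 7.77 or more in every other array, untreated ones included. The low wild type DEN level makes the size and rank of its changes here and below depend on the offset, with 4.86 at an offset of 1 and 3.37 at 50 in N750F against wild type.

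All 38 G2/M genes were higher in N750F when adjusted over the list alone, and 30 of them passed over all genes, with 8 not passing and a median of 1.97. The list mean differed by 2.01 (95% interval 1.07 to 2.94, list adjusted p = 6.99e-47, adjusted p = 0.0742 with an estimated correlation). Cenpf, a kinetochore protein, differed by 3.16 ± 0.38 and Nusap1, of the spindle, by 2.41 ± 0.34. Of 38 E2F targets of DNA replication, 11 were higher and 27 did not pass (33 adjusted over the list alone, median 1.06, adjusted p = 0.0742 with an estimated correlation). Leading were Prim1, the DNA primase subunit (2.35 ± 0.35), and Pole2, of DNA polymerase epsilon (2.03 ± 0.28). Chek1, the S and G2 checkpoint kinase, at 2.13 ± 0.30 was the member called among 33 DNA repair genes, of which 32 did not pass (8 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation). Rbl1, which encodes the p107 pocket protein, at 1.39 ± 0.29 was the member called among 25 genes of the RB family and E2F system, with 24 not passing (4 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation). In the p53 list the mean differed by 0.13 (95% interval -0.17 to 0.44), with no call for the list.

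On the metabolic side, 6 of 30 cytochromes P450 and drug metabolism genes were lower and 24 did not pass (7 lower adjusted over the list alone, adjusted p = 0.0742 with an estimated correlation), among them Cyp2c38 (-1.85 ± 0.25) and Cyp2f2 (-1.27 ± 0.22). NRF2 and glutathione genes had 2 lower of 27, Gstm1 (-0.93 ± 0.20) and Gstm3 (-0.87 ± 0.20), with 25 not passing (7 lower adjusted over the list alone, adjusted p = 0.238 with an estimated correlation). Of 15 circadian clock genes 3 were lower, among them Nr1d2 (-1.14 ± 0.22) and Per3 (-1.11 ± 0.22), 1 was higher, Arntl, the BMAL1 gene (1.29 ± 0.28), and 11 did not pass, with no call for the list (adjusted p = 0.216). Fetal liver and imprinted growth genes had 3 higher of 15 and 12 not passing, Igf2, Peg3 (1.95 ± 0.33) and Mest (1.42 ± 0.26), with 7 higher adjusted over the list alone (adjusted p = 0.0742 with an estimated correlation).

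Macrophage and Kupffer cell markers were higher than in wild type DEN livers as well: 3 of 16 passed and 13 did not (9 higher adjusted over the list alone, adjusted p = 0.0742 with an estimated correlation). Their list mean was 8.21 in N750F, 7.43 in wild type DEN and 8.45 in untreated livers. The 3 were Vsig4 (1.65 ± 0.27), Lyz2 (1.15 ± 0.20) and cathepsin S, Ctss (1.02 ± 0.20), although the N750F and wild type ranges overlapped for Vsig4 and Ctss. Endothelial, stellate and interferon lists had medians of 0.27, 0.23 and 0.22 with 0, 1 and 0 members called by limma and 0, 3 and 0 adjusted over the list alone (adjusted p = 0.238, 0.153 and 0.41 with an estimated correlation). The stellate member was the collagen gene Col3a1 (1.31 ± 0.28). The interferon median became -0.055 without wild type DEN array 3. Within batches, each with a single wild type array, the difference of the G2/M list mean was 1.89 in batch 1 and 2.15 in batch 2. Neither batch alone measures the spread of wild type DEN arrays. Without wild type DEN array 4, whose spread was the widest, 2 genes were called, and without wild type DEN array 3 there were 494. Leaving out N750F arrays 2, 3 or 5 gave 112, 141 or 105 and leaving out a knockout-labelled array 319.

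**Figure D3:**
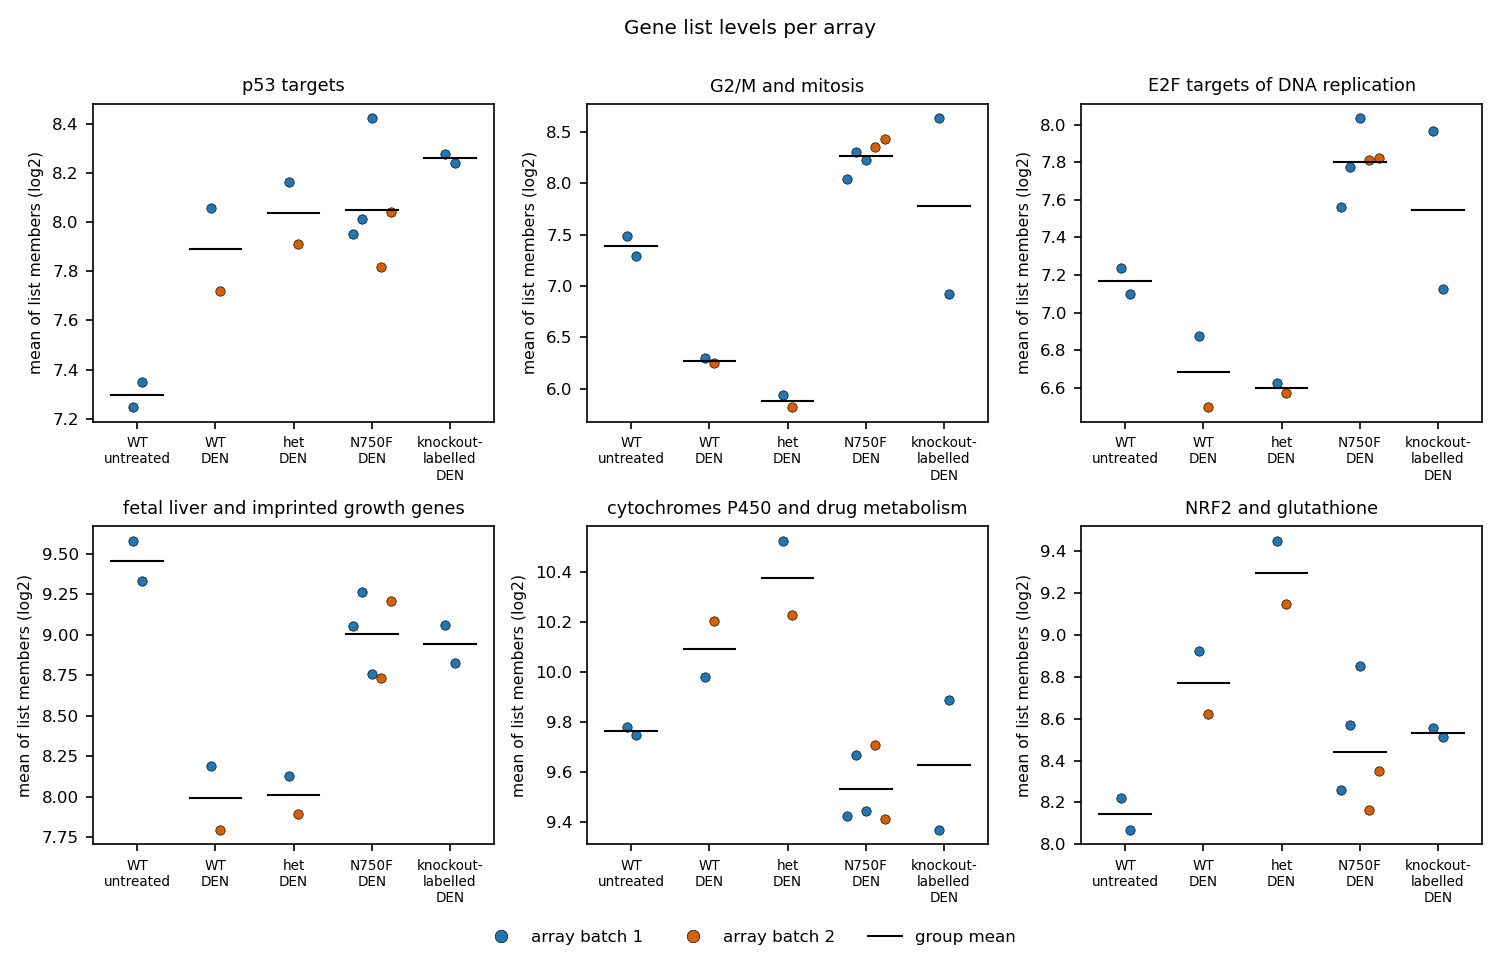
Mean log2 level of the members of 6 gene lists (y axis) in each of the 13 arrays by group (x axis), with the group mean as a line and the array batch as the colour; WT is wild type and het is heterozygous. For the G2/M list the N750F mean was 8.27 against 6.27 in wild type DEN, 5.88 in heterozygous DEN and 7.39 in untreated livers, and the 2 knockout-labelled arrays lay at 8.64 and 6.93.

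Against heterozygous livers after DEN, N750F livers had 195 genes higher and 50 lower. Mitotic genes led the higher side: Birc5 (4.27 ± 0.61), Anln (3.66 ± 0.47), the proliferation antigen Mki67 (3.55 ± 0.40), Ube2c (3.47 ± 0.38), the spindle motor Kif11 (3.43 ± 0.51) and topoisomerase II alpha, Top2a (3.29 ± 0.49), together with Igf2 (3.70 ± 0.41). The lower side was led by Sult1e1 (-5.19 ± 0.48), Akr1c19 (-3.22 ± 0.42), the acute phase gene Orm1 (-3.18 ± 0.34), Cyp2c38 (-3.15 ± 0.25), Gstt3 (-2.78 ± 0.40) and Cyp1a1 (-2.22 ± 0.24). Adjusted p-values of these 13 ran from 7.79e-05 for Cyp2c38 to 0.00357, and all 5 N750F arrays lay beyond both heterozygous arrays for each. A second Top2a probe set was dim, at a mean of 5.27, and differed by 0.32.

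Of 38 G2/M genes, 32 were higher and 6 did not pass (all 38 higher adjusted over the list alone), with a median of 2.37 and a list mean difference of 2.40 (95% interval 1.46 to 3.34). The list adjusted p was 2.74e-65, and adjusted p = 0.0436 with an estimated correlation. Among E2F targets 16 of 38 were higher and 22 did not pass (33 adjusted over the list alone, adjusted p = 0.0449 with an estimated correlation), such as Chaf1a, of the chromatin assembly factor (1.84 ± 0.27), and Dnmt1, the maintenance DNA methyltransferase (1.34 ± 0.21). The 3 DNA repair genes called of 33 were Chek1 (2.21 ± 0.30), Brca1 (1.99 ± 0.35) and Brca2 (1.40 ± 0.31), with 30 not passing and 11 adjusted over the list alone (adjusted p = 0.138 with an estimated correlation). E2f7 (1.40 ± 0.28), E2f8 (2.27 ± 0.52), Ccne2 (1.40 ± 0.30) and Rbl1 (1.29 ± 0.29) were the 4 called among 25 genes of the RB family and E2F system, with 21 not passing (5 adjusted over the list alone, adjusted p = 0.172 with an estimated correlation).

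Detoxification genes were lower in N750F than in heterozygous livers. Of 27 NRF2 and glutathione genes, 10 were lower and 17 did not pass (16 adjusted over the list alone, median -0.88, adjusted p = 0.0378 with an estimated correlation), with Ugdh at -1.84 ± 0.25, the aldehyde oxidase Aox1 at -1.71 ± 0.29 and Gstm1 at -1.57 ± 0.20. Cytochromes P450 and drug metabolism had 5 lower of 30 and 25 not passing (13 adjusted over the list alone, median -0.57, adjusted p = 0.0378 with an estimated correlation). Among 15 fetal liver and imprinted genes 3 were higher and 12 did not pass, Igf2, Mest (2.01 ± 0.26) and alpha-fetoprotein, Afp (2.87 ± 0.66), with 9 higher adjusted over the list alone (adjusted p = 0.0706 with an estimated correlation). Macrophage markers had 1 called of 16, Ctss (0.93 ± 0.20), and endothelial markers 1 of 18, Stab1 (0.93 ± 0.20), with 15 and 17 not passing and 7 and 1 adjusted over the list alone (adjusted p = 0.116 and 0.172 with an estimated correlation). The 26 fatty acid oxidation genes had a median of 0.16 with 0 called by limma and 2 adjusted over the list alone (adjusted p = 0.172 with an estimated correlation). The erythroid list mean differed by 0.15 (95% interval -0.15 to 0.45). Within batches, each with a single heterozygous array, the G2/M difference was 2.26 in batch 1 and 2.57 in batch 2. Neither batch alone measures the spread of heterozygous arrays. The Y-linked covariate gave 54 genes. Without heterozygous array 4 there were 18 genes and without heterozygous array 3 there were 149.

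In knockout-labelled against wild type livers after DEN, 7 genes were higher and 0 lower by limma, among 1278 genes at an unadjusted p under 0.05. They were Akr1c18 (5.09 ± 0.59), Cenpf (3.11 ± 0.48), Bex3 (2.63 ± 0.38), the securin gene Pttg1 (2.36 ± 0.34), the antiproliferative gene Btg1 (2.11 ± 0.32), Ccnb2 (2.02 ± 0.31) and Tceal9 (1.87 ± 0.26), with adjusted p-values of 0.0102 to 0.0343 (2 arrays against 2). Both knockout-labelled arrays lay above both wild type arrays for each. All 7 were also called higher in N750F against wild type livers, which uses the same wild type arrays. Of 38 G2/M genes, 2 were higher and 36 did not pass (28 adjusted over the list alone, median 1.55, adjusted p = 0.182 with an estimated correlation). The list mean differed by 1.54 (95% interval 0.36 to 2.72). This interval pools the spread of all groups and may be too narrow, since the 2 knockout-labelled arrays lay far apart. E2F targets had a median of 0.79 with 38 not passing (13 adjusted over the list alone, adjusted p = 0.182 with an estimated correlation). Fetal, macrophage and stellate lists had medians of 0.68, 0.72 and 0.32 and cytochrome P450, NRF2 and cholesterol synthesis lists medians of -0.39, -0.36 and -0.38, with no member of these lists called by limma. Adjusted over the list alone, 6, 6 and 0 genes of the first lists were higher and 6, 0 and 0 of the others lower. With an estimated correlation the adjusted p was 0.182, 0.19, 0.19, 0.182, 0.305 and 0.355 in that order. Igf2, at 2.66 ± 0.52 (adjusted p = 0.11), did not pass.

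The 2 knockout-labelled arrays lay apart in proliferation genes, with a G2/M list mean of 8.64 in array 1 and 6.93 in array 2 and all 38 genes lower in array 2, the array that held muscle transcripts. The G2/M and E2F medians against wild type were 0.62 and 0.39 without array 1. Counts were 92 without knockout-labelled array 2, 48 without array 1 (26 higher and 22 lower, 4 of the 7 among them), 73 without wild type DEN array 3, 0 without wild type DEN array 4 (limma) and 1 to 2 without N750F array 2, 3 or 5, and batch 1 alone gave 2. With the Y-linked covariate 0 genes were called, and batch 2 held no knockout-labelled array.

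Knockout-labelled against heterozygous livers, both groups being male, had 33 genes higher and 12 lower. Ube2c (3.59 ± 0.47), Nusap1 (3.07 ± 0.43), Cenpf (2.81 ± 0.48) and Sgo2a, a protector of centromere cohesion (2.79 ± 0.35), were the largest on the higher side. The largest on the lower side were Sult1e1 (-3.84 ± 0.60), Orm1 (-3.19 ± 0.42), Akr1c19 (-2.97 ± 0.53) and Cyp2c38 (-2.49 ± 0.31), and these 8 had adjusted p-values of 0.00689 to 0.0419. Of 38 G2/M genes, 9 were higher and 29 did not pass (37 adjusted over the list alone, median 1.82, adjusted p = 0.113 with an estimated correlation). Of 38 E2F targets 1 was higher, Chaf1a (2.39 ± 0.34), with 37 not passing (15 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). Cyp2c38, Ugt2b1 (-1.89 ± 0.29) and Cyp1a1 (-1.73 ± 0.30) were the 3 lower of 30 cytochromes P450 and drug metabolism genes, with 27 not passing (7 adjusted over the list alone, adjusted p = 0.0665 with an estimated correlation). Gstm1 (-1.32 ± 0.25) was lower among 27 NRF2 and glutathione genes, with 26 not passing and 17 adjusted over the list alone (adjusted p = 0.0665 with an estimated correlation). Gpc3 (1.82 ± 0.33) was higher among 15 fetal genes, with 14 not passing and 4 adjusted over the list alone (adjusted p = 0.137 with an estimated correlation). Macrophage genes had a median of 0.51 with 0 of 16 called by limma and 0 adjusted over the list alone (adjusted p = 0.485 with an estimated correlation). Without knockout-labelled array 1 the G2/M and E2F medians were 0.94 and 0.50, and 55 genes were called (29 higher and 26 lower, 16 of the 45 among them). The count was 135 without knockout-labelled array 2, which held muscle transcripts, 2 without heterozygous array 4, 12 without heterozygous array 3, and 14 to 26 without any single untreated, wild type DEN or N750F array. Batch 1 alone, with a single heterozygous array, called not any of the 45 genes, the Y-linked covariate gave 19 genes, and batch 2 held no knockout-labelled array.

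Heterozygous and wild type livers after DEN differed in 1 gene, Akr1c18, which was higher in heterozygous livers by 5.01 ± 0.56 (adjusted p = 0.00641, 2 arrays against 2), with 1029 genes at an unadjusted p under 0.05. Both heterozygous arrays lay above both wild type arrays. The NRF2 and glutathione list had a median of 0.60 with no member called by limma and 2 higher adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), and its mean differed by 0.53 (95% interval 0.12 to 0.93). For G2/M genes the median was -0.35, with 0 called by limma and 0 adjusted over the list alone (adjusted p = 0.987 with an estimated correlation). Heterozygous mice were male and wild type mice female, so sex and genotype changed together, and with the Y-linked covariate 0 genes were called. Akr1c18 itself was low in the wild type DEN arrays alone, as given above. It was higher in every other array, those of female N750F and untreated mice included, which argues against sex alone for this gene. Without wild type DEN array 4 limma called 0, and without wild type DEN array 3 or heterozygous array 3 there were 131 and 21. Without heterozygous array 4 the count was again 1, but it was another gene, which was lower, and Akr1c18 did not pass. In each batch alone, with a single array per group, Akr1c18 was not called.

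N750F against knockout-labelled livers gave 0 genes by limma at an adjusted p under 0.05, with 1823 at an unadjusted p under 0.05, and 5 when limma's trend and robust options were used. The smallest p-values, which did not pass, belonged to the metallothioneins Mt1 (-1.90 ± 0.29) and Mt2 (-1.59 ± 0.24) and to Dpysl2 (-1.46 ± 0.22), each with an adjusted p of 0.0739. The lists for E2F targets, G2/M, DNA repair and interferon response had medians of 0.22, 0.44, 0.30 and 0.32, and those for the acute phase, immediate early genes and skeletal muscle -0.19, -0.34 and -0.52, with an adjusted p = 0.698 with an estimated correlation for each of the 7. Adjusted over the list alone, 3 acute phase, 2 immediate early and 1 muscle gene were lower and 0 of the others passed in limma. The G2/M list mean differed by 0.46 (95% interval -0.52 to 1.45). Without knockout-labelled array 1 there were 511 genes and without array 2, which held muscle transcripts, there were 4. The E2F and G2/M medians became -0.18 and -0.40 without array 2. Leaving out heterozygous array 3 or 4 gave 2 genes, and batch 1 alone gave 0 by limma, batch 2 holding no knockout-labelled array.

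Whether N750F and the knockout label changed the same genes was asked across the 14953 genes, which are not independent replicates. N750F minus heterozygous and knockout-labelled minus wild type, which share no array, correlated with Pearson's r = 0.252 and Spearman's rho = 0.129, against 0.0271 (range -0.00797 to 0.0690) for unchanged groups in 100 simulations. The simulations drew each gene independently, so their ranges here and below do not tell how far r moves when genes vary together. The covariance was 0.0515 against 0.00300 in the simulations. Of the 195 and 7 genes called higher, 4 were shared, where 0.0913 would be shared by independent lists. With wild type as the shared control, r was 0.603 and rho 0.514 against a simulated 0.590 (0.562 to 0.611), and the covariance was 0.126 against 0.0652. All 7 genes were then shared, where 0.0791 would be by independent lists. Part of this excess may come from the shared controls, which were too few to split. The first r was 0.0225 without knockout-labelled array 1 and 0.423 without array 2, and the second was 0.305 and 0.732. No r could be had in batch 2, which held no knockout-labelled array.

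**Figure D4:**
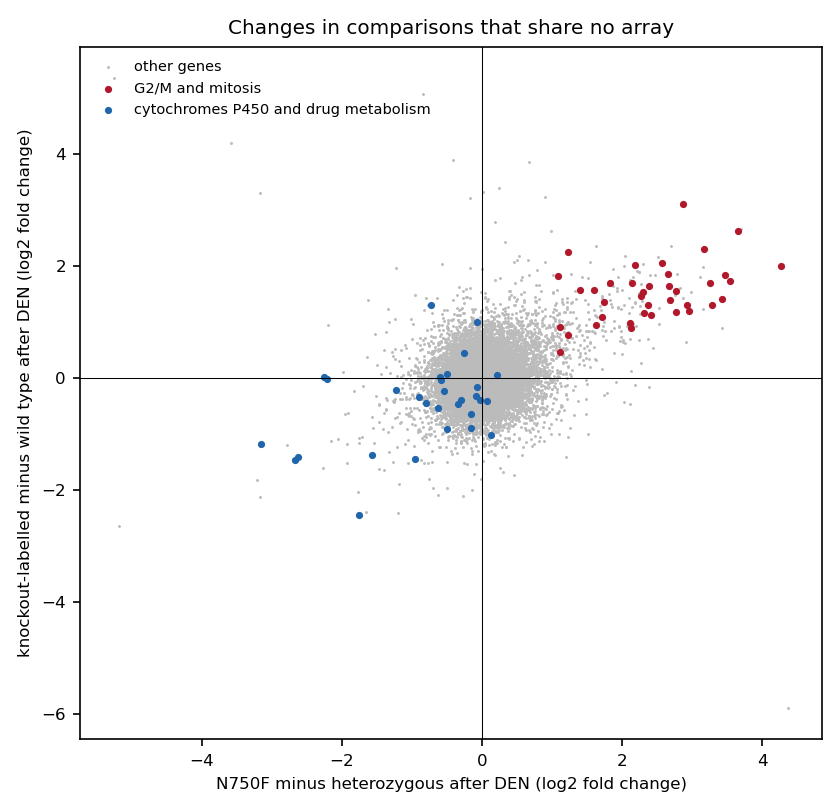
Log2 change of each tested gene in N750F minus heterozygous livers (x axis) and in knockout-labelled minus wild type livers (y axis) after DEN, comparisons that share no array, with G2/M genes in red, cytochromes P450 and drug metabolism genes in blue and other genes in grey. The G2/M genes, with medians of 2.37 and 1.55, lay in the upper right, and the far grey points at the lower right and upper left were Xist (4.38 and -5.89) and Y-linked genes such as Kdm5d (-3.59 and 4.21), in which the sexes of the mice differed.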

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

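N750F after DEN was the group with enough arrays (5) to ask whether an array stood apart. Over 148 items, 26 lists and 122 named genes, the array farthest from the others lay beyond Dixon's limit for 5 genes and 0 lists, and chance alone marks about 1 in 20. In N750F array 4, Ccnb2, cyclin B2, was at 8.97 with the nearest array at 8.45. The same array had Esco2, a cohesin acetyltransferase, at 8.62 with the nearest at 8.01, and Slc16a1, a monocarboxylate transporter, at 9.51 with the nearest at 9.01. In N750F array 3, Polk was at 10.18 with the nearest at 9.41, and Srxn1, sulfiredoxin, at 9.84 with the nearest at 8.42. The levels were not adjusted for batch. N750F array 4, of batch 2, had the lowest median intensity of all arrays (48.2) and the largest share of values below the offset (22%). No explanation of these values was tested.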

How the results depend on the processing

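The tests without normalization, with offsets of 1 and 50, without the 2 arrays of widest spread, and all of the comparisons of other genotypes with untreated livers were chosen after the data were seen. Over all alternatives, 5845 values of named genes kept their direction and side of the threshold, 17 passed it newly, 2437 no longer passed and 1 changed sign, and of the list values 1655 kept both, 188 no longer passed, 4 changed sign and 1 reversed in its test but not in its median. Most lost gene calls came from settings with fewer arrays, whose own construction lowers the power, and for the others the cause was not tested. Counts of called genes were moved by over 1.5 times in no comparison by dropping the filter, using all probe sets or requiring a fold change of 2. Signal over background limits the dim genes, for which the offset decides the size of a change.

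Counts below are genes called, against 103 for DEN in wild type, 7 for knockout-labelled and 212 for N750F against wild type, 245 for N750F and 45 for knockout-labelled against heterozygous, 1 for heterozygous against wild type, 0 for N750F against knockout-labelled, and 210, 928 and 13 for heterozygous, N750F and knockout-labelled against untreated. They name the comparisons in that order where they moved by over 1.5 times, and the cause was not tested. A count need not hold the genes of the main fit. In batch 1 alone, DEN and the N750F and knockout-labelled comparisons with heterozygous livers shared no call with it. In batch 2 alone, heterozygous against wild type shared no call with it.

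Without the batch term DEN gave 37, N750F against wild type 104, N750F against heterozygous 146, knockout-labelled against heterozygous 23, and the comparisons with untreated livers 65, 82 and 1, and the r of N750F and knockout-labelled changes with no shared array was 0.345. Batch 1 alone gave DEN 1, knockout-labelled against wild type 2, N750F against wild type 0, N750F and knockout-labelled against heterozygous 1 and 1, heterozygous against wild type 0, and against untreated 2, 286 and 7. Batch 2 alone gave N750F against heterozygous 112 and heterozygous against wild type 6, and the comparisons with untreated or knockout-labelled arrays could not be run in it. Batch as a random block gave N750F against untreated 364, with a correlation of 0.235 within batches.

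With the replicate number as a block, DEN gave 0, knockout-labelled against wild type 0, N750F against wild type 36, N750F against heterozygous 114, knockout-labelled against heterozygous 0, N750F against knockout-labelled 1, heterozygous against untreated 9 and N750F against untreated 16. The numbers were not taken as pairs: the labels do not say so, and numbers 3 and 4 coincide with the batches in part. Of 12 same-number pairs 7 had deviations from the group mean that correlated above 0.1 (range -0.131 to 0.452, median 0.201, against 0.10 for 24 pairs of other numbers within a batch). These deviations carry the batch difference, and N750F array 2 and heterozygous array 3, of other numbers, correlated at 0.457. The correlations therefore cannot tell whether the numbers mark pairs.

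The 50th percentile filter gave knockout-labelled against untreated 20. Median centring gave DEN 63, knockout-labelled against wild type 3 and against heterozygous 14, and heterozygous against untreated 115. Trend and robust options gave DEN 211, knockout-labelled against wild type 11, N750F against knockout-labelled 5, and heterozygous and knockout-labelled against untreated 368 and 31. Array weights gave knockout-labelled against wild type 1 and against heterozygous 25, and against untreated 564, 2730 and 8. An adjusted p under 0.10 gave DEN 255, knockout-labelled and N750F against wild type 20 and 388, knockout-labelled against heterozygous 75, N750F against knockout-labelled 4, and against untreated 496, 1672 and 43.

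The Y-linked covariate gave DEN 26, knockout-labelled against wild type 0, N750F and knockout-labelled against heterozygous 54 and 19, heterozygous against wild type 0, and heterozygous and knockout-labelled against untreated 100 and 7. No normalization gave DEN 22, knockout-labelled against wild type 1 and against heterozygous 14, and against untreated 71, 438 and 8. An offset of 1 gave DEN 50, knockout-labelled against wild type 1 and against heterozygous 14, and heterozygous and N750F against untreated 112 and 532. An offset of 50 gave DEN 192, knockout-labelled against wild type 15, N750F against knockout-labelled 3, and heterozygous and knockout-labelled against untreated 340 and 25. Without the 2 arrays of widest spread DEN gave 10, knockout-labelled and N750F against wild type 0 and 0, N750F and knockout-labelled against heterozygous 10 and 1, N750F against knockout-labelled 2, and against untreated 17, 311 and 7. The 2 groups alone gave DEN 4, knockout-labelled against heterozygous 2, heterozygous against wild type 5, and heterozygous and knockout-labelled against untreated 13 and 0.

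Scaling moved the split of calls: N750F against untreated went from 578 higher and 350 lower to 543 and 178 with median centring and 319 and 119 without normalization, DEN from 45 and 58 to 13 and 9 without normalization, and heterozygous against untreated from 101 and 109 to 41 and 30. The median change of all genes stayed within 0.1 of its main value.

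Leaving out 1 array at a time, where a group left with a single array is assumed to vary like the others, gave from 4 to 226 for DEN, 0 to 92 and 2 to 494 for knockout-labelled and N750F against wild type, 18 to 314 and 2 to 135 for N750F and knockout-labelled against heterozygous, 0 to 131 for heterozygous against wild type, 0 to 511 for N750F against knockout-labelled, and 28 to 407, 13 to 1355 and 0 to 46 against untreated. The r with no shared array ran from 0.0225 to 0.423 and that with shared controls from 0.305 to 0.820. Signs changed in 5 log2 values and the test alone reversed for 1, and the cause was not tested. The interferon list in N750F against wild type ran from -0.055 (without wild type DEN array 3) to 0.64. In knockout-labelled against untreated livers the E2F list ran from 0.030, where the test but not the median reversed, to 0.82 and the G2/M list from -0.31 to 1.30, lowest without knockout-labelled array 1. In N750F against knockout-labelled livers the same lists ran from -0.18 to 0.68 and from -0.40 to 1.11, lowest without array 2. Rb1 in knockout-labelled against heterozygous livers ran from -1.28 to 0.070, highest without array 2.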

Other observations

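Apart from the fit with the Y-linked covariate, which had been chosen earlier, the tests of explanations in this part were chosen after the results were seen.

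Genes that responded to DEN in wild type liver, leaving out p53 targets, were followed through the other genotypes. The 40 higher genes had a median log2 change against untreated livers of 1.77 in wild type, where they were chosen, 1.62 in heterozygous, 1.11 in N750F and 1.12 in knockout-labelled livers, and the 58 lower genes -1.87, -1.61, -0.82 and -0.87, all against the untreated arrays used to choose them. In N750F against heterozygous livers, whose groups share no array with those of the DEN comparison but enter its estimates of spread and batch, 30 of the 40 lay below 0 and 46 of the 58 above 0. Across 14953 genes, which are not independent replicates, N750F minus heterozygous and the DEN response in wild type correlated with r = -0.164 and rho = -0.0370, against -0.0264 (range -0.0698 to 0.0110) in simulations of unchanged groups. Each gene was drawn independently in them, so that range may be too narrow. Of the genes called in both, 13 were higher in N750F and lower after DEN, where 0.756 would be by independent lists. Another 10 were lower in N750F and higher after DEN, where 0.150 would be, and 0 were called the same way.

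Members of lists without a call were read as single genes. In N750F against heterozygous livers 2 of 16 fatty acid synthesis genes were higher, the elongase Elovl5 (1.51 ± 0.25) and the desaturase Fads2 (1.27 ± 0.26), and 14 did not pass (list adjusted p = 0.0849). In the same comparison 1 of 15 circadian clock genes was higher, Arntl (1.29 ± 0.28), 2 were lower, Per3 (-1.27 ± 0.22) and Nr1d2 (-1.05 ± 0.22), and 12 did not pass (list adjusted p = 0.181). In knockout-labelled against heterozygous livers Per3 and Nr1d2 were lower (-1.67 ± 0.28 and -1.42 ± 0.27) and 13 clock genes did not pass (list adjusted p = 0.445). Mt1 was lower in N750F than untreated livers by 2.77 ± 0.29 (log2 change -2.77, adjusted p = 0.000629). In knockout-labelled array 2, Mylpf, Tnni2 and Acta1, all of skeletal muscle, were at 10.18, 9.98 and 8.68 against at most 5.79, 6.13 and 5.90 in the other arrays, whereas Ckm, Atp2a1 and Myl1 of the same list were not highest there.

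The G2/M genes were higher in N750F than in heterozygous livers after DEN, by 2.40 for the list mean (95% interval 1.46 to 3.34), with 32 of 38 called and an adjusted p = 0.0436 with an estimated correlation. With the Y-linked level as a covariate the difference was 2.37 (0.95 to 3.80), so sex, which varied within the untreated and N750F groups alone, does not account for the whole of it. The erythroid list differed by 0.149 (-0.15 to 0.45), but it held 7 of its 19 genes, without globins, at a mean of 6.53 in N750F livers near the filter limit of 5.94, so erythroid precursors stay open. Without the 2 arrays of widest spread, array 4 of wild type DEN and of heterozygous DEN, the difference was 2.26 (0.62 to 3.89), but 1 heterozygous array was left and was assumed to vary like the other groups, so a share of these arrays in it stays open. The 2.26 without these arrays is the same estimate as that within batch 1 given earlier, so it is not a separate check. Without them the batch 2 arrays of N750F have no control and inform the batch term alone. Genotype, litter, developmental stage and other dividing cells stay open as untested.

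Fetal and imprinted genes were higher in N750F than in wild type livers after DEN, by 0.99 for the list mean (95% interval 0.55 to 1.43), with 3 of 15 called, 12 not passing and an adjusted p = 0.0742 with an estimated correlation. Less exposure to DEN in N750F animals cannot be told apart from other differences: the p53 list differed by 0.135 (-0.17 to 0.44), against a rise of 0.71 with DEN in wild type, but the other DEN genes above had smaller medians in N750F (1.11 and -0.82) than in heterozygous livers (1.62 and -1.61). Without the 2 arrays of widest spread the fetal difference was 0.836 (0.11 to 1.56), with 1 wild type DEN array left that was assumed to vary like the other groups, so these arrays stay open too. No untreated N750F array was analysed here, so a difference that was there before DEN stays open. Maturity of the litters would act on the same genes and was not tested.

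The 2 knockout-labelled arrays lay apart in G2/M genes, with a median difference of -1.60 (array 2 minus array 1) and all 38 genes lower in array 2. Dilution by muscle RNA in array 2, where 8 of 11 muscle genes were highest, would have lowered hepatocyte genes about as much, and their median difference was 0.0198 (quartiles -0.28 to 0.28). Rb1 itself was lower in array 2 by a log2 difference of -1.35, against a residual SD of 0.196 in the other groups. The G2/M list mean was 8.64 in array 1 and 6.93 in array 2. It cannot tell which array lost Rb1, because the effect of that loss on G2/M genes is itself what these arrays measure. Incomplete deletion or a wrong label in one of them cannot be told apart from other differences between the mice, because each array is alone in its kind and the position of the Rb1 probe set was not known. No biological explanation was tested here.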
